A study of Homo sapiens with 12 samples.

How the data were processed

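Expression was measured in LNCaP cells, a line derived from a lymph node metastasis of prostate cancer, on Affymetrix U133A and U133B arrays, which carry mostly different probe sets. There were 12 samples in 3 groups, which had received a GFP control cDNA, a SOX4 cDNA or a pool of siRNAs against SOX4. Each group had 2 arrays per array type, 1 for each of 2 days. RNA was taken 24 hours after transfection with the lipid reagent DMRIE-C, per the labels' protocols.

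The deposited values are on a log2 scale and were made by the authors with GCRMA, per the submitters' processing notes; its version is not given in the sources used here. GCRMA corrects each probe for background from its sequence, normalizes the arrays and gives 1 value per probe set. The log2 scale was read from the values, whose medians lay between 4.23 and 4.36 on U133A and between 3.35 and 3.59 on U133B. The sources used here do not say whether the 6 arrays of a table were processed together. Each table was tested alone, and levels were not compared between the tables. Arrays give no count of molecules, so for depth it can only be said that the number of arrays, 2 per group, limits the precision.

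Values were used as deposited. U133A held 22283 probe sets and U133B 22645, of which 68 on each were Affymetrix controls and were left out of the tests. Probe sets whose mean over the 6 arrays lay at or above the 40th percentile were tested: 13329 on U133A (a mean of at least 3.57) and 13546 on U133B (at least 3.14). Gene symbols came from the probe annotation supplied with the tables. On U133A 19071 probe sets had 1 symbol, 1043 had several and 2169 had none; on U133B these were 15432, 554 and 6659. No symbol needed an update to the RefSeq names. The probe sets tested with 1 symbol covered 8035 genes on U133A and 6927 on U133B.

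Differences were tested in R 4.3.3 with limma 3.58.1, by a linear model with a mean per group over the 6 arrays of a table and empirical Bayes variances with an intensity trend, which left 3 residual degrees of freedom. All limma p-values are two-sided and were adjusted by the Benjamini-Hochberg method within a table and comparison, with a threshold of 0.05. Probe sets that differed at least 2-fold the same way on both days were counted as a description without a test. The day was not in the model. The study's design text states that transfections were made on separate days, so that arrays of the same day form pairs. The deviations of same-day arrays from their group means had correlations across probe sets of 0.354, 0.261 and 0.245 on U133A and 0.555, 0.482 and 0.496 on U133B. A model with the day as a block was one of the alternatives.

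Gene lists were 34 sets written before the data were examined, among them androgen response, signalling, cell cycle, stress and metabolic lists and markers of prostate basal cells, fibroblasts and leukocytes that a culture could hold. They were tested with limma's camera at a preset inter-gene correlation of 0.01, with 1 probe set per gene (the highest mean) and at least 5 measured genes. This gave 31 lists on U133A and 22 on U133B, while 3 and 12 lists were too small. Adjustment was over the lists of a table and comparison. The sign of a list test is relative to the other genes of the table. Each list also has the number of members with an adjusted p under 0.05 when p-values were adjusted over the list alone.

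Named genes were chosen by a rule also written before the data were examined. SOX4 came first with every probe set. Then came, per comparison, the 8 highest and 8 lowest differences on U133A and the 4 highest and 4 lowest on U133B among probe sets that passed. Where fewer passed, places were filled by the smallest p among probe sets that differed at least 2-fold the same way on both days. From each list that passed, up to 4 members with the smallest p were named.

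The correlation between the differences from GFP in the SOX4 cDNA and SOX4 siRNA groups was compared with 100 simulations of unchanged groups against the same GFP arrays, since these comparisons share their controls. The simulated counts of probe sets at least 2-fold apart in both groups, without a day effect and with the spread left by a model that holds the day, were added after the results were seen. Control probe sets for 18S and 28S ribosomal RNA (12), for spike-in RNA added before hybridization (18) and for the 3' and 5' ends of ACTB and GAPDH were averaged per array.

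The limma script was tested on simulated data for the comparison of SOX4 cDNA with GFP, with 200 changed probe sets in each of 20 simulations. On U133A (13329 probe sets) it called 6.9% of true log2 changes of 1, 76.7% of changes of 2, 98.6% of changes of 3 and 99.8% of changes of 4. On U133B (13546 probe sets) the shares were 36.8%, 76.4%, 91.1% and 98.2%. A shift of 0.5 in a list of 30 genes was called in 20 of 20 simulations on both array types. With no shift such a list was called in 1 of 20 on U133A and 0 of 20 on U133B. The simulated genes varied independently, so this does not show how often a list of correlated genes is called without a shift. The simulated spread was the empirical Bayes spread, without a day effect, and the shares depend on how many probe sets were changed. They are thus not the shares of real changes that would be called. RAB11B, at -3.63 in SOX4 cDNA against GFP, did not pass (limma adjusted p = 0.219).

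Alternatives were the day as a block, no filter, a filter at the 60th percentile, no intensity trend, robust variances, quantile normalization, median-centred arrays, only the 4 arrays of the groups compared, 1 probe set per gene, adjustment over both tables together, camera with an estimated correlation, the mean of a gene's probe sets, and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9. Sequences of the transfected cDNA, the siRNAs and the probes were not used here.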

Results

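RNA from LNCaP cells was profiled after transfection with a GFP control cDNA, with a SOX4 cDNA, which raises the amount of this HMG-box transcription factor, or with a pool of siRNAs against SOX4, which lowers it. Each of the 3 groups had 2 arrays of each array type, from transfections on 2 days, so every mean has n = 2. The limma p-values of probe sets rest on the spread between these 2 days' samples, pooled over the 3 groups and moderated across probe sets. The camera p-values of lists set a list's genes against the other genes at the preset correlation. They are not a measure of the spread between the days. With an estimated correlation camera rests on the 3 residual degrees of freedom, so a list can hardly pass. A call not held there is therefore left unchecked, neither upheld nor refuted. The labels name no aim beyond the design. The comparisons ask which transcripts differ when SOX4 is raised, when it is lowered, and between those states. The median over all probe sets ranged from 4.23 to 4.36 log2 on U133A and from 3.35 to 3.59 on U133B. Between the days of a group the arrays had correlations across probe sets of 0.965 (GFP), 0.930 (SOX4 cDNA) and 0.975 (SOX4 siRNA) on U133A, and of 0.952, 0.966 and 0.986 on U133B. The U133A array of SOX4 cDNA on day 2 stood apart, with a mean correlation with the other arrays of 0.919, against 0.940 to 0.951 for the rest.

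The GFP arrays differed from both SOX4 groups in their control probe sets. Probe sets for 18S and 28S ribosomal RNA had a mean of 5.34 ± 1.66 log2 (SD) in GFP, 9.88 ± 0.10 in SOX4 cDNA and 9.71 ± 0.13 in SOX4 siRNA on U133A, and 5.59 ± 1.84, 10.64 ± 0.09 and 10.55 ± 0.10 on U133B. Probe sets for spike-in RNA, which is added and does not come from the cells, had 11.38 ± 0.13, 9.77 ± 0.74 and 9.20 ± 0.46 on U133A, and 11.76 ± 0.28, 10.43 ± 0.47 and 9.93 ± 0.22 on U133B. The signal at the 3' end of ACTB, the beta-actin transcript, exceeded that at its 5' end by 1.10 ± 0.33 in GFP, 2.65 ± 0.75 in SOX4 cDNA and 1.31 ± 0.39 in SOX4 siRNA on U133A, and by 1.06 ± 0.14, 2.49 ± 0.64 and 1.38 ± 0.05 on U133B. A larger excess is a common sign of RNA that is degraded or incompletely copied. For GAPDH the 3' minus 5' difference on U133A was -0.32 ± 0.30 in GFP, -0.06 ± 0.22 in SOX4 cDNA and 0.14 ± 0.12 in SOX4 siRNA. On U133B it was 0.04 ± 0.01, 0.64 ± 0.23 and 0.54 ± 0.12. Unlike that of ACTB, it was thus not clearly larger in SOX4 cDNA than in SOX4 siRNA.

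**Figure D1:**
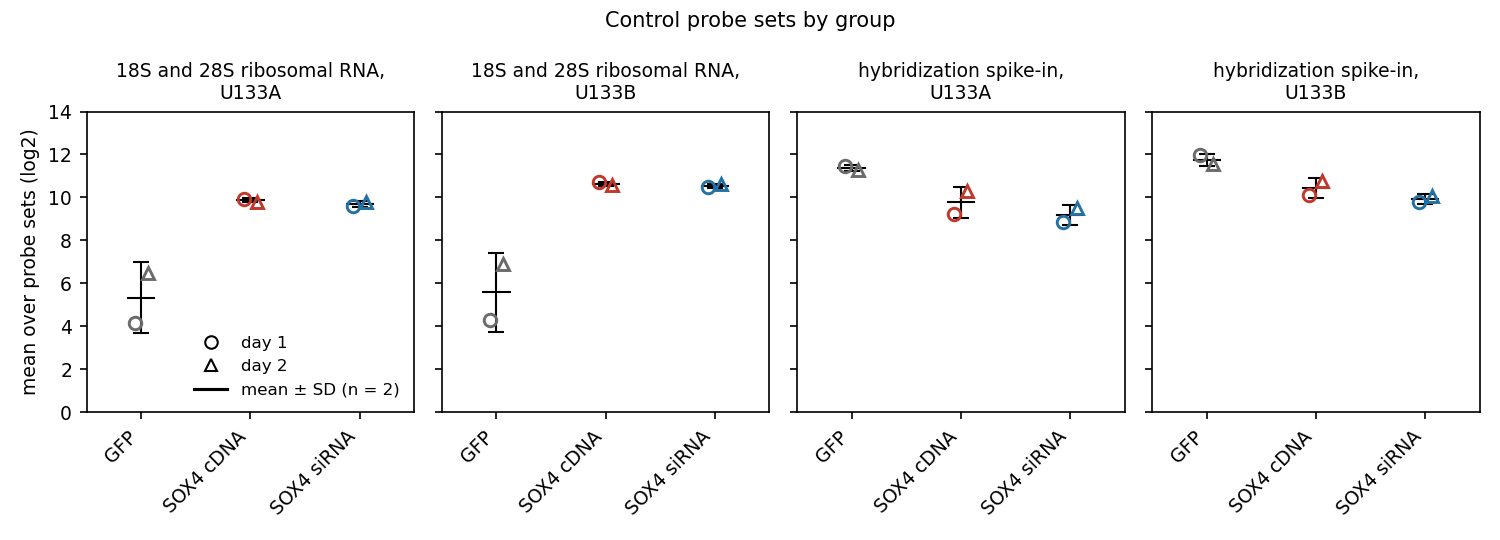
Mean deposited log2 value (vertical axis) of the 12 ribosomal RNA and 18 spike-in probe sets in the 3 transfection groups, for U133A and U133B; points are the arrays of day 1 and day 2, and bars are the mean ± SD (n = 2). Ribosomal RNA signal in the GFP group (5.34 on U133A) lies below that of both SOX4 groups (9.88 and 9.71), and spike-in signal (11.38) lies above theirs (9.77 and 9.20).

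SOX4 itself was read by 5 probe sets, all on U133A. With the SOX4 cDNA, 1 of them, called the high-rising probe set below, rose from 2.74 ± 0.04 to 14.97 ± 0.79 log2 (SD), a difference of 12.23 ± 0.41 (SE) with a limma adjusted p of 0.000351. The GFP value lay at the 19.7th percentile of the array, near background, and the day 2 value with the cDNA, 15.53, was the highest of its array, so the ratio of 4795-fold depends on both ends of the scale. The other 4 SOX4 probe sets did not pass in that comparison and differed by 1.38, 0.70, 0.36 and -0.61. The probe set at 1.38 read 7.46 and 10.01 on the 2 SOX4 cDNA arrays. With the siRNA pool all 5 probe sets were lower than in GFP on both days, though the high-rising one was near background in both groups and carries little weight. The log2 differences were -2.51 ± 0.30 (the probe set at -0.61 with the cDNA), -1.62 ± 0.32, -1.37 ± 0.75, -1.16 ± 0.35 and -0.48 ± 0.41 (the high-rising one). None of these passed over all probe sets, with a limma adjusted p of 0.106 for the probe set at -2.51, and 3 passed when adjusted over the SOX4 probe sets alone, a choice made after the values were seen. Of the SOX C family, the SOX genes closest to SOX4, SOX12 was the other member measured of the 3 listed and differed by -0.71 ± 0.32 in SOX4 cDNA and 0.71 ± 0.32 in SOX4 siRNA against GFP, neither passing. Where the probe sets lie in relation to the transfected sequence was not used here.

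**Figure D2:**
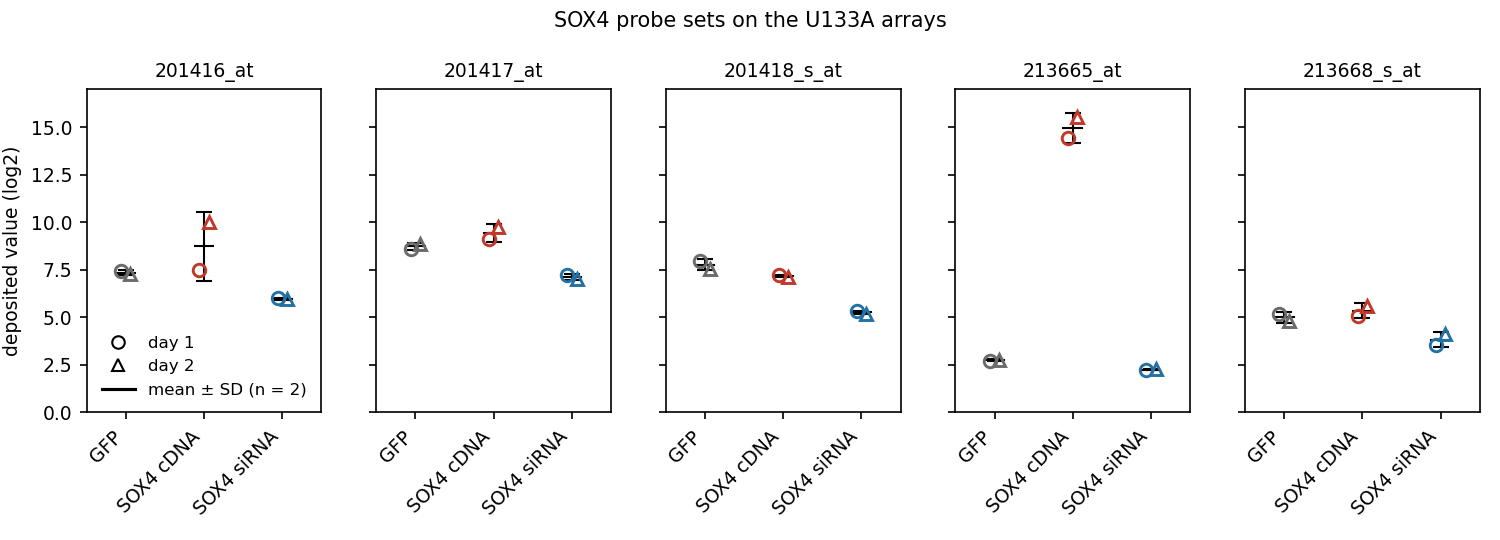
Deposited log2 value (vertical axis) of the 5 SOX4 probe sets on U133A in the 3 transfection groups; points are the arrays of day 1 and day 2, and bars are the mean ± SD (n = 2). The high-rising probe set reaches 14.97 in the SOX4 cDNA group against 2.74 in GFP. All 5 probe sets are lower in SOX4 siRNA than in GFP on both days, the high-rising one near background in both.

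In the cells given SOX4 cDNA, genes of the androgen response, the programme that the androgen receptor drives in luminal prostate cells, were lower than in the GFP cells. Of 26 measured genes on U133A, 16 were lower on both days and 2 were higher, with a median log2 difference of -0.20 and a mean of -0.49; of all tested probe sets 33.2% were lower on both days. The list fell by limma's camera test (adjusted p = 0.00402), a call not held with an estimated correlation (adjusted p = 0.923 with an estimated correlation). KLK3, which encodes prostate-specific antigen, differed by -1.20 ± 0.23 (SE), ELL2, a transcription elongation factor, by -1.74 ± 0.46, PMEPA1, an androgen-induced transmembrane protein, by -1.04 ± 0.29, and MAF, a transcription factor, by -0.96 ± 0.29, with its SOX4 cDNA mean under the testing limit of 3.57. None of the 26 passed over all probe sets, and KLK3 alone passed when adjusted over the list alone (0.0387). Further probe sets differed by -1.57 and, on U133B, -0.29 for KLK3, by -0.23 and -0.33 on U133B for PMEPA1, by -0.03 for MAF and by 0.05 at most on U133B for ELL2. On U133B the same list had 16 genes and a median of -0.21 and did not pass (adjusted p = 0.702). In these arrays the 3' excess of ACTB was 1.55 higher than in GFP on U133A, ribosomal RNA signal was 4.54 higher and spike-in signal differed by -1.61. The 3' minus 5' difference of GAPDH was 0.25 higher. The list did not pass in SOX4 cDNA against SOX4 siRNA, which holds no GFP array. By the U133A probe sets named, ELL2, PMEPA1 and MAF were also lower than in GFP (6.81, 9.88 and 4.45) with the siRNA pool (5.61, 8.94 and 3.56). KLK3 was not (12.83 in GFP and 12.90 with the siRNA pool). A U133B probe set of ELL2 went the other way, with 4.40 in GFP and 5.69 with the siRNA pool. The direction of ELL2 with the siRNA pool is thus open. Without GFP replicate 1 the list no longer passed (median -0.11, adjusted p = 0.149); the median was -0.44 without GFP replicate 2 and -0.49 without SOX4 cDNA replicate 1.

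No other list passed for SOX4 cDNA against GFP. The p53 targets, genes of cell cycle arrest and DNA repair, had a median of 0.36 (adjusted p = 0.202), histones -0.18 (0.168), interferon-stimulated genes -0.26 (0.311), small RNA processing factors 0.48 (0.327), Notch pathway genes -0.35 (0.414), immediate early genes 0.40 (0.343) and markers of epithelial-mesenchymal transition 0.39 (0.537). Beta-catenin and TCF pathway genes had a median of 0.18, and Wnt ligands and receptors -0.05 (adjusted p = 0.617 for both). The NF-kappaB targets had a median of 0.31 but a mean of -0.05 and a test direction below the other genes (adjusted p = 0.889). Likewise fatty acid synthesis genes had a median of 0.04 with a mean of -0.15, and ribosome biogenesis genes a median of -0.01 with a mean of 0.04.

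Only SOX4, by its high-rising probe set, passed among the 13329 probe sets of U133A in this comparison, and limma called 0 of the 13546 on U133B; 1513 and 2063 had an unadjusted p under 0.05, where chance alone gives 666 and 677. Apart from SOX4, 23 named genes ranked first among those that differed at least 2-fold on both days, with limma adjusted p-values of 0.176 to 0.247. All 23 also differed from the same GFP arrays in the same direction in the SOX4 siRNA group, so they are not read as particular to the SOX4 cDNA. The higher values included FOLH1, which encodes prostate-specific membrane antigen, at 2.38 ± 0.31, PIK3C2B, a class II PI3-kinase, at 2.15 ± 0.26, NFIB, a transcription factor, at 2.45 ± 0.33, MPDZ at 2.35, JADE2 at 2.48 and SHROOM2 at 1.86, with SLC18B1 (2.39), ZC3H12C (1.80), MRPL41 (1.29) and TBL1XR1 (1.79) on U133B. The lower values included RAB11B, a GTPase of recycling endosomes, at -3.63 ± 0.44, MAP2K2, the kinase MEK2, at -2.87 ± 0.35, FKBP8 at -2.19, WIZ at -2.35, PEX10 at -2.46 and CLIC4 at -1.82, with YIF1B (-2.89), FBRS (-1.94), ITGB8-AS1 (-1.19) and LRATD1 (-1.10) on U133B. HSP90B1, an endoplasmic reticulum chaperone, was at 3.15 by 1 probe set and at -1.98 by another, so its direction is open. Other probe sets also had the opposite sign for JADE2 (-0.28), MPDZ (-0.15), NFIB (-0.42), CLIC4 (0.05), MRPL41 (-0.39), TBL1XR1 (-0.27 and -0.55) and YIF1B (0.04). H2BC12L, at -1.59, is a histone gene with near-identical copies and is uncertain. For PIK3C2B, SHROOM2, CLIC4, MRPL41 and ITGB8-AS1 the lower of the 2 group means lay under the testing limit (3.57 on U133A and 3.14 on U133B), so the sizes of these differences are not exact. Of the 33 further probe sets of the named genes, 24 had the same sign and 9 the opposite. On U133A 188 probe sets were at least 2-fold higher on both days and 255 lower, and on U133B 202 and 63. On single days 1165 (day 1) and 2637 (day 2) differed by as much on U133A, and 773 and 1246 on U133B; between the 2 days of the SOX4 cDNA group 2522 and 1197 did.

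In the cells given the siRNA pool, genes of hypoxia and glycolysis were higher than in the GFP cells. Of 29 measured genes on U133A, 25 were higher on both days and 2 lower, where 37.3% and 33.6% of all tested probe sets were, with a median log2 difference of 0.82 (0.69 on day 1 and 0.90 on day 2). The list rose by limma's camera test (adjusted p = 3.91e-06), a call not held with an estimated correlation (adjusted p = 0.748 with an estimated correlation). P4HA1, a collagen prolyl hydroxylase, differed by 1.95 ± 0.34 (SE), PDK1, which holds back pyruvate oxidation, by 2.11 ± 0.46, PFKFB3, which speeds glycolysis, by 2.07 ± 0.46 and the glycolytic enzyme ALDOA by 0.91 ± 0.14. None passed over all probe sets, and 8 of the 29 passed, all higher, when adjusted over the list alone. On U133B 7 of 10 genes of this list were higher on both days, with a median of 0.93. Of the list's 32 measured genes 3 were on U133B only, so most of these were also read on U133A, in the same RNA. The U133B adjusted p by camera was 0.0529, and 0.0433 with the day as a block. With an estimated correlation no list passed on U133B in this comparison (smallest camera adjusted p = 0.851). Ribosomal RNA signal was 4.37 higher than in GFP and spike-in signal differed by -2.18 on U133A, while the 3' excess of ACTB was 0.21 higher and that of GAPDH 0.46 higher; on U133B these were 0.33 and 0.50 higher.

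Cell-division genes were also higher in the siRNA group on U133A, mostly through day 2, while neither list passed on U133B. The G2/M and mitosis list rose on U133A, with 21 of 33 genes higher on both days and 3 lower, and a median of 0.81 (adjusted p = 0.019 by camera; adjusted p = 0.786 with an estimated correlation). Its median was 0.22 on day 1 and 1.37 on day 2. The mitotic kinase CDK1 differed by 1.97 ± 0.67, the checkpoint gene MAD2L1 by 1.71 ± 0.35 (-0.24 by its U133B probe set), the spindle motor KIF11 by 1.70 ± 0.55 and DLGAP5 by 1.64 ± 0.57. The G1/S and DNA replication list rose too, with 18 of 30 genes higher on both days and 4 lower, and a median of 0.53 (adjusted p = 0.0325; adjusted p = 0.748 with an estimated correlation). CCNE2, a cyclin of S phase entry, differed by 2.76 ± 0.55, POLE2 by 1.90 ± 0.45, RRM2 by 1.14 ± 0.36 and SLBP by 1.13 ± 0.40. On U133B, with 7 genes each, the medians were -0.17 for G2/M (3 higher and 4 lower on both days, adjusted p = 0.745) and -0.07 for G1/S (1 higher and 3 lower, adjusted p = 0.623). On U133A no member of either list passed over all probe sets or when adjusted over the list alone. Without GFP replicate 2 neither list passed (a median of 0.18 and adjusted p = 0.721 for G2/M, and a median of 0.07 for G1/S), nor without SOX4 siRNA replicate 1 (0.107 and 0.158); without GFP replicate 1 the medians were 1.39 and 0.95. The G1/S list also missed the threshold after quantile normalization (0.0573) and with the mean of a gene's probe sets (0.0663), and both missed it with a filter at the 60th percentile (0.0706 for G2/M and 0.0871 for G1/S).

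Genes of 2 basic cell functions rose as lists in the siRNA group on U133A and NF-kappaB targets fell. Oxidative phosphorylation genes, which encode the mitochondrial respiratory chain, had a median of 0.35, with 22 of 35 higher on both days and 3 lower (adjusted p = 0.00985; adjusted p = 0.748 with an estimated correlation). The complex I subunits NDUFS3, NDUFS1, NDUFA1 and NDUFB8 differed by 1.15 ± 0.31, 1.04 ± 0.31, 0.97 ± 0.26 and 0.89 ± 0.23, though NDUFS1 also had probe sets at -0.21 and -0.29. The mRNA splicing genes had a median of 0.48, with 24 of 36 higher on both days and 5 lower (adjusted p = 0.00985; adjusted p = 0.748 with an estimated correlation). SF3A1 differed by 1.17 ± 0.33, SF3A3 by 1.15 ± 0.27 and SRSF1 by 1.03 ± 0.23. The direction of 3 splicing genes is open: SF3A1 had other probe sets at -0.75 and -0.16, SRSF1 at -0.15 and -0.27, and PNN was at -0.94 ± 0.25 by 1 probe set and at 0.84 by another. On U133B the medians were 0.01 for oxidative phosphorylation (adjusted p = 0.836) and 0.20 for splicing (0.556). Both lists also leaned higher in SOX4 cDNA against the same GFP arrays on U133A, without passing. There 20 of 36 splicing genes were higher on both days and 7 lower (median 0.20, camera adjusted p = 0.35). For oxidative phosphorylation 15 of 35 were higher and 6 lower (median 0.13, 0.537). Splicing did not pass in SOX4 cDNA against SOX4 siRNA (median -0.23, 0.206), so its rise is not read as particular to the siRNAs. The NF-kappaB and inflammatory targets had a median of -0.35, with 9 of 14 lower on both days and 1 higher (adjusted p = 0.0128; adjusted p = 0.748 with an estimated correlation). NFKB2, a subunit of the factor itself, differed by -1.98 ± 0.44 and passed when adjusted over the list alone (0.0426), though its other probe set differed by -0.13. Most of this fall was shared with SOX4 cDNA, with NFKB2 means of 7.46 (GFP), 5.73 (SOX4 cDNA) and 5.48 (SOX4 siRNA). NFKB1 was at -0.74 ± 0.30, the cytokine LIF at -0.89 ± 0.41 and the chemokine CCL2 at -0.80 ± 0.37. The SOX4 cDNA means of NFKB1, LIF and CCL2 (6.61, 6.21 and 6.66) were near or above those of GFP (6.69, 5.67 and 6.69). For oxidative phosphorylation and splicing no gene passed when adjusted over the list alone. Without GFP replicate 2 splicing (0.259, with a median of 0.28) and NF-kappaB (0.316) did not pass, without SOX4 siRNA replicate 1 splicing (0.107) and oxidative phosphorylation (0.0967) did not, and after quantile normalization none of the 3 did (0.0573 for splicing and for NF-kappaB, 0.0821 for oxidative phosphorylation). Oxidative phosphorylation also missed the threshold with a filter at the 60th percentile (0.0521). The NF-kappaB median was -0.64 without SOX4 siRNA replicate 2.

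The other lists did not pass for SOX4 siRNA against GFP: TGF-beta and SMAD pathway genes had a median of -0.16 (adjusted p = 0.0722), histones -0.31 (0.0909), androgen response genes -0.06 (0.271) and interferon-stimulated genes, which long or impure siRNAs can induce, -0.09 (0.287). Signs of median and mean or test were mixed for Wnt ligands and receptors (median 0.09, mean 0.03, test below the other genes), for beta-catenin and TCF pathway genes (median -0.07, mean 0.23) and for the Notch pathway (mean -0.06).

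Among single probe sets limma called 0 for SOX4 siRNA against GFP on either array type, with 2032 of 13329 on U133A and 2694 of 13546 on U133B at an unadjusted p under 0.05. The 23 named genes other than SOX4 had adjusted p-values of 0.0538 to 0.123. All 23 also differed from the same GFP arrays in the same direction in the SOX4 cDNA group, so they are not read as particular to the siRNAs. The higher values included PCMT1, a protein repair methyltransferase, at 3.39 ± 0.26, SHROOM2 at 2.86 ± 0.24, PLOD2, a collagen lysyl hydroxylase, at 2.51 ± 0.25, the nuclear envelope gene TMPO at 2.68 ± 0.29, FBXW2 at 2.85, PLEKHB2 at 2.30 and DAZAP2 at 1.97, with TBL1XR1, a corepressor subunit, at 3.13 ± 0.15, the transcription factor YY1 at 2.67 ± 0.19, SLC18B1 at 2.90 and VPS36 at 1.16 on U133B. The lower values included STX3, a membrane fusion protein, at -2.59 ± 0.29, C1orf116 at -2.22 ± 0.30, and on U133B PSD4 at -1.53, LRATD1 at -1.08, TMEM25 at -1.15 and FRG1JP at -1.25. Named genes with probe sets on opposite sides of GFP included AGRN (-3.24 and 1.19), AKT2 (-3.59 and 1.13), ARID1A (-2.21 and 0.63), EGFR (-1.51 and 0.95) and COX5B (1.97 and -1.49). Other probe sets also had the opposite sign for PCMT1 (-0.01), FBXW2 (-0.13), DAZAP2 (-0.10 and -0.47), VPS36 (-0.31), TMEM25 (0.16) and FRG1JP (0.34). H2BC15, at -2.43, is a histone gene with near-identical copies and is uncertain. For SHROOM2, PLOD2, AGRN, ARID1A, H2BC15, AKT2, EGFR and VPS36 the lower group mean lay under the testing limit (3.57 on U133A and 3.14 on U133B), so these sizes are not exact. Of 50 further probe sets of the named genes 33 had the same sign and 17 the opposite. At least 2-fold on both days, 548 probe sets were higher and 239 lower on U133A, and 396 and 37 on U133B; after quantile normalization these were 414 and 302, and 258 and 72, and with median-centred arrays 412 and 322 on U133A. At an unadjusted p under 0.05 the higher share on U133A was 67.2%, against 54.1% after quantile normalization and 55.0% with median-centred arrays. On U133B it was 32.5%, against 42.9% after quantile normalization, and for SOX4 cDNA against GFP it was 29.8%, against 39.9%. These shares turned with the filter: on U133B they were 60.3% (SOX4 siRNA) and 53.7% (SOX4 cDNA) with a filter at the 60th percentile and 16.7% and 19.3% with no filter, and the U133A share for SOX4 siRNA was 76.4% and 48.0%, so no majority direction is read from them. The median over all U133A probe sets moved from 0.03 to -0.09 with median-centred arrays, under which 7 probe sets passed as higher and 8 as lower. Among these were PCMT1 (adjusted p = 0.0128), SHROOM2 (0.0429), AGRN (0.0299), STX3 (0.0429) and the SOX4 probe set at -2.51 (0.0429).

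**Figure D3:**
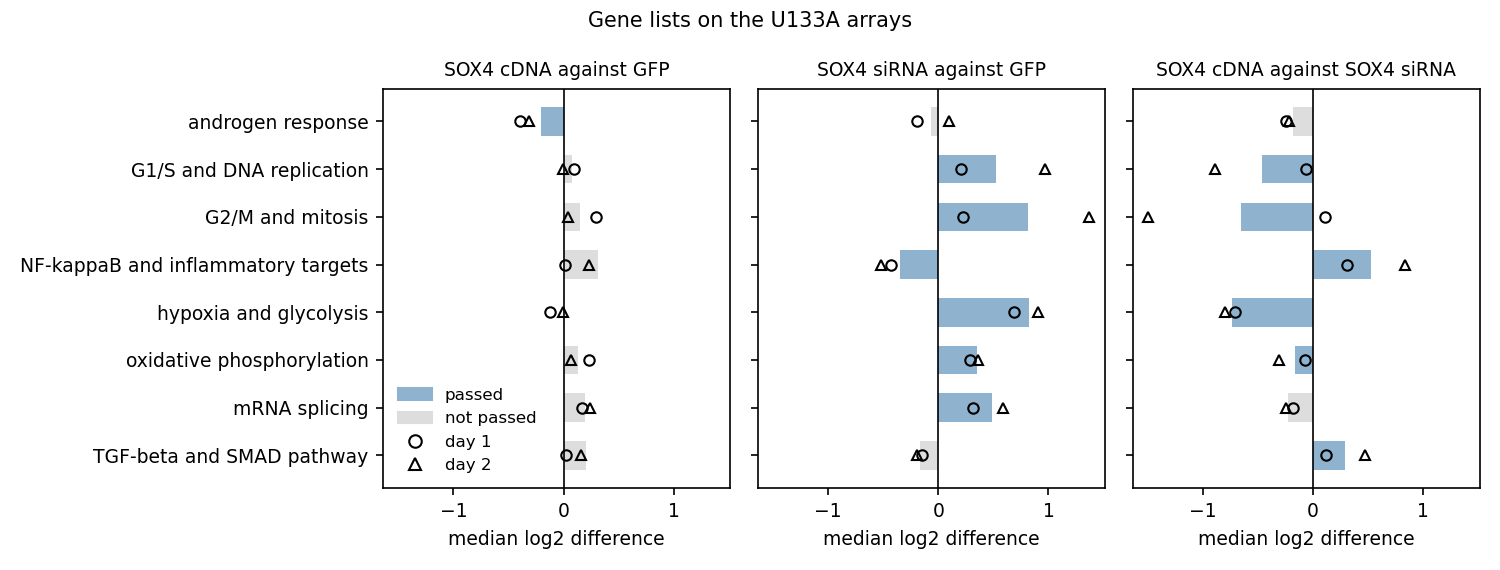
Median log2 difference (horizontal axis) of the genes of each list that passed in any comparison on U133A; bars are the difference of group means, blue where the list passed camera at the preset correlation and grey where it did not, and symbols are the medians on day 1 and day 2. Hypoxia and glycolysis genes lie at 0.82 in SOX4 siRNA against GFP and at -0.73 in SOX4 cDNA against SOX4 siRNA, with both days on the same side, while the G2/M list moves from 0.11 on day 1 to -1.49 on day 2 in the latter.

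Set directly against each other, the SOX4 groups also differed in the hypoxia and glycolysis list, in a comparison that shares the siRNA arrays with the one above. Hypoxia and glycolysis genes were lower with SOX4 cDNA than with SOX4 siRNA on U133A, 21 of 29 on both days against 1 higher, with a median of -0.73 (-0.71 on day 1 and -0.79 on day 2). The list fell by limma's camera test (adjusted p = 1.06e-07), a call not held with an estimated correlation (adjusted p = 0.958 with an estimated correlation). The glycolytic enzymes PKM, ENO1 and ALDOA differed by -1.21 ± 0.19 (SE), -1.01 ± 0.20 and -0.73 ± 0.14 and P4HA1 by -1.50 ± 0.34, an ENO1 probe set was at 0.22, and 8 genes, all lower, passed when adjusted over the list alone. Of the list's 32 measured genes 3 were on U133B only. Most of its 10 genes on U133B were thus read on both array types, in the same RNA, and are not independent support. On U133B the list also fell, with 6 of 10 genes lower on both days, 1 higher and a median of -1.04 (camera adjusted p = 0.0157, and 0.794 with an estimated correlation). There PDK1 differed by -2.16 ± 0.66, PFKFB4, a regulator of glycolysis, by -1.42 ± 0.31, ALDOA by -1.07 ± 0.32, and ANKRD37, a hypoxia target, by -1.99 ± 0.54 with its other probe set at 1.02; none passed when adjusted over the list alone. Ribosomal RNA signal differed by 0.17 between these groups on U133A and by 0.09 on U133B, and the 3' excess of ACTB was 1.34 and 1.11 higher with SOX4 cDNA. The 3' minus 5' difference of GAPDH did not follow, at -0.21 on U133A and 0.09 on U133B for SOX4 cDNA against SOX4 siRNA. The U133B call was lost without SOX4 cDNA replicate 1 (0.268) or SOX4 siRNA replicate 1 (0.0787); the U133B median was -0.67 without SOX4 cDNA replicate 2 and -0.01 with no filter, where the list still passed (0.0205).

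**Figure D4:**
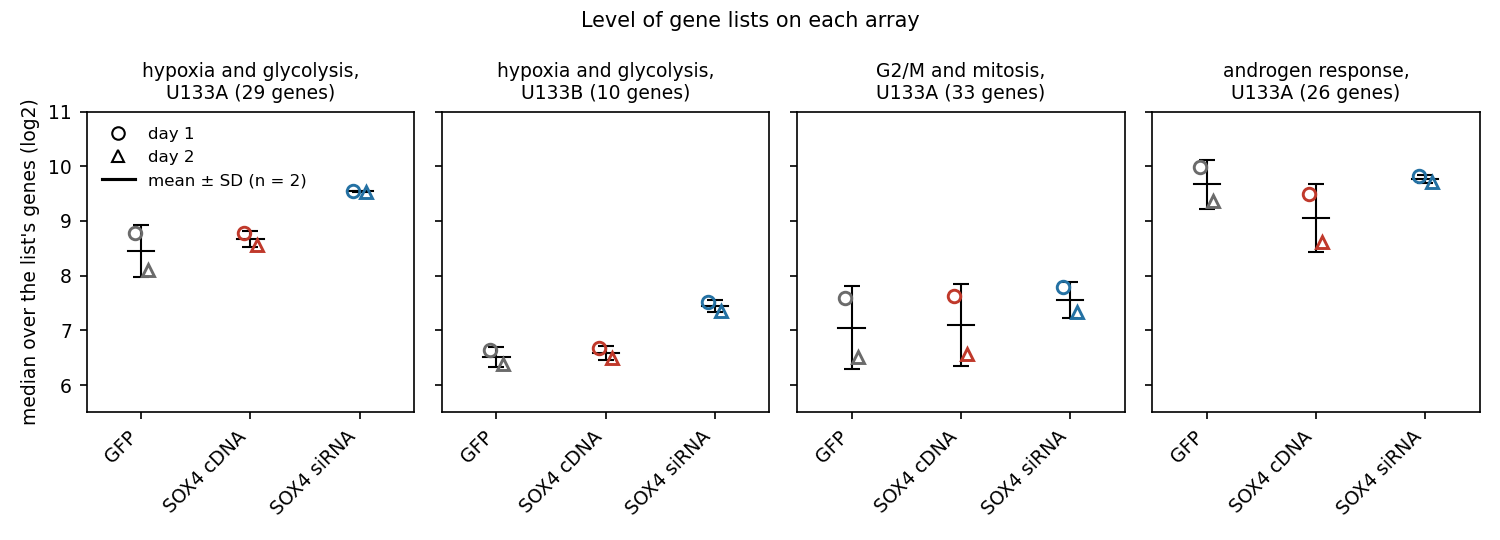
Median deposited log2 value (vertical axis) over the genes of a list in the 3 transfection groups; points are the arrays of day 1 and day 2, and bars are the mean ± SD (n = 2). Hypoxia and glycolysis genes lie at 9.55 and 9.54 on the SOX4 siRNA arrays of U133A, above GFP (8.78 and 8.11) and SOX4 cDNA (8.78 and 8.56), whereas G2/M genes on U133A are lower on day 2 than on day 1 in every group.

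TGF-beta and SMAD pathway genes were higher with SOX4 cDNA than with SOX4 siRNA. The list rose on U133A, with 9 of 15 genes higher on both days and 0 lower and a median of 0.29 (adjusted p = 0.00418 by camera; adjusted p = 0.958 with an estimated correlation). TGFBR2, a receptor of the pathway, differed by 1.47 ± 0.50, TGIF1, a SMAD corepressor, by 1.20 ± 0.36 and ID1, a target of BMP signals, by 1.07 ± 0.33; the SOX4 siRNA mean of TGFBR2 lay under the testing limit of 3.57, as did the SOX4 cDNA mean of CCL5 below. On U133B, over 7 genes, the median was 0.25 (adjusted p = 0.49). BMP7 was at 1.31 ± 0.44 by 1 probe set and at -0.80 by another, so its direction is open. The NF-kappaB targets rose as well, with 8 of 14 genes higher on both days and 3 lower and a median of 0.52 (adjusted p = 0.0291; adjusted p = 0.958 with an estimated correlation): TNFAIP3, a brake on this pathway, differed by 1.60 ± 0.59, LIF by 1.43 ± 0.41 and CSF1 by 1.42 ± 0.43, while CCL5 was at -1.40 ± 0.53, with its other probe set at 0.43. No member of either list passed when adjusted over the list alone. The 3' excess of ACTB was 1.34 higher with SOX4 cDNA on U133A and 1.11 on U133B, and highest, at 3.19, on U133A in SOX4 cDNA replicate 2. The 3' minus 5' difference of GAPDH was -0.22 on that array, below both SOX4 siRNA arrays (0.06 and 0.23). Without that array, which also stood apart, neither list passed (0.136 and 0.323), and the NF-kappaB list did not pass without GFP replicate 1 (0.128, with a median of 0.34), without a filter (0.052) or after quantile normalization (0.0756). Without SOX4 cDNA replicate 1 the medians were 0.52 (TGF-beta) and 0.79 (NF-kappaB).

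The cell-division and respiratory lists fell in SOX4 cDNA relative to SOX4 siRNA on U133A. Of the G2/M and mitosis genes 13 of 33 were lower on both days and 3 higher, with a median of -0.65 (adjusted p = 0.021; adjusted p = 0.958 with an estimated correlation), which was 0.11 on day 1 and -1.49 on day 2. CDK1 differed by -1.67 ± 0.67, DLGAP5 by -1.49 ± 0.57, BUB1, a spindle checkpoint kinase, by -1.24 ± 0.63 and MAD2L1 by -1.11 ± 0.35. Of the G1/S and DNA replication genes 15 of 30 were lower on both days and 2 higher, with a median of -0.47 (adjusted p = 0.021; adjusted p = 0.958 with an estimated correlation), which was -0.06 on day 1 and -0.89 on day 2. CDC45, part of the replicative helicase, differed by -2.22 ± 0.99, CCNE2 by -1.69 ± 0.55, POLE2 by -1.06 ± 0.45 and MCM7 by -0.75 ± 0.31. Of the oxidative phosphorylation genes 16 of 35 were lower on both days and 2 higher, with a median of -0.16 (adjusted p = 0.0455, and 0.063 with the day as a block; adjusted p = 0.958 with an estimated correlation). CYC1 of complex III differed by -1.41 ± 0.46, COX7B of complex IV by -0.78 ± 0.23 (0.31 by its U133B probe set), NDUFS3 by -0.71 ± 0.31 and NDUFA1 by -0.62 ± 0.26. On U133B the medians were -0.10 for G2/M (adjusted p = 0.49), -0.18 for G1/S (0.259) and -0.01 for oxidative phosphorylation (0.942). On U133A no member of the 3 lists passed when adjusted over the list alone. The 3' excess of ACTB was 1.34 higher with SOX4 cDNA on U133A and stood at 3.19 in SOX4 cDNA replicate 2, where the 3' minus 5' difference of GAPDH was -0.22. Without SOX4 cDNA replicate 2 none of the 3 passed (0.610, 0.861 and 0.692) and the medians of the cell-division lists turned to 0.10 (G2/M) and 0.02 (G1/S); without SOX4 siRNA replicate 1 they did not pass either (0.122, 0.123 and 0.270). Without SOX4 cDNA replicate 1 the medians were -1.49, -1.01 and -0.37. The oxidative phosphorylation call also ended with a filter at the 60th percentile (0.179), quantile normalization (0.48), median-centred arrays (0.108) and the mean of a gene's probe sets (0.0722).

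The high-rising SOX4 probe set was the one that passed for SOX4 cDNA against SOX4 siRNA, at 12.71 ± 0.41 (limma adjusted p = 0.000272); the siRNA value, 2.26, lay below the GFP value near background, so the size of this difference is not exact. The other 4 SOX4 probe sets differed by 2.75, 2.33, 1.91 and 1.52. On U133B limma called 0 probe sets. An unadjusted p under 0.05 was reached by 1437 on U133A and 501 on U133B, where chance alone gives 666 and 677. With the day as a block these counts were 2115 and 1190, so the low U133B count depends on leaving the day out. The 23 further named genes had adjusted p-values of 0.230 to 0.661. Higher with SOX4 cDNA were the values of TBXT, the transcription factor brachyury, at 3.72 ± 0.57 (adjusted p = 0.0222 without SOX4 cDNA replicate 1), PIK3C2B at 1.66 ± 0.26 and GM2A, a lysosomal lipid-binding protein, at 2.08 ± 0.34, with MRPL41 (1.13), CREBRF (1.42), ATG10 (1.35), an autophagy gene, and ENPP5 (1.41) on U133B. Other probe sets had the opposite sign for AGRN (2.57, with -1.26 and -0.22), ARID1A (2.01, with -0.06 and -0.23), PPP2R1B (1.79, with -0.61 and -0.02) and MRPL41 (-0.73 and -0.71), and among the lower genes for CHD9 (0.24, 0.25 and 0.75), TMED2 (0.26) and GSE1 (0.06). H2AC14 (2.48) is a histone gene with near-identical copies and is uncertain. Lower were PLOD2 at -2.36 ± 0.25, TMPO at -2.43 ± 0.29, SGPP1, a sphingosine phosphate phosphatase, at -2.61 ± 0.36, FAM13A at -1.74, PCMT1 at -1.98, TMED2 at -1.72 and GSE1 at -2.16, with PPP1R9A (-1.34), TBL1XR1 (-1.34), CHD9 (-1.29) and ELL2 (-1.24) on U133B. For TBXT, whose SOX4 siRNA mean was 1.56, and for AGRN, ARID1A, PLOD2, FAM13A and PPP1R9A the lower group mean lay under the testing limit (3.57 on U133A and 3.14 on U133B), so these sizes are not exact. Of 45 further probe sets of the named genes 32 had the same sign and 13 the opposite. On U133A 315 probe sets were at least 2-fold lower on both days, and fewer were higher; on U133B 22 were higher and 102 lower. After quantile normalization 157 were higher and 229 lower on U133A, and 31 and 71 on U133B, and with median-centred arrays 172 and 245 on U133A. At an unadjusted p under 0.05 the higher share on U133A was 35.1%, against 45.8% after quantile normalization.

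Against GFP, the SOX4 cDNA and SOX4 siRNA groups differed in the same direction at most probe sets. FOLH1 was at 2.38 with the cDNA and 2.28 with the siRNAs, SLC18B1 at 2.39 and 2.90, and LRATD1 at -1.10 and -1.08, all against the same GFP arrays. Across 13329 probe sets of U133A the correlation of the differences was 0.554 (Spearman 0.541). In simulations of unchanged groups that shared simulated GFP arrays it was 0.497 (0.474 to 0.520). On U133B, across 13546 probe sets, it was 0.753 (0.741), against 0.499 simulated (0.470 to 0.531). In these simulations every group had the same spread at a probe set. Between the days 1558 probe sets of GFP, 1197 of SOX4 cDNA and 248 of SOX4 siRNA differed at least 2-fold on U133B. On U133A these were 1158, 2522 and 736. A larger spread in the shared GFP arrays would raise the correlation, the covariance and the shared counts, so the excess on U133B may be overstated. Probe sets are not independent replicates. The covariance was 0.217 on U133A, against 0.104 simulated, and 0.193 on U133B, against 0.067. The correlation within a day was 0.482 on day 1 and 0.517 on day 2 on U133A, and 0.741 and 0.703 on U133B. Probe sets with the same sign made up 70.1% on U133A, against 66.6% simulated, and 80.5% on U133B, against 66.7%. At least 2-fold higher in both groups on both days were 75 probe sets on U133A, against a mean of 17.1 and at most 27 in the simulations, and 114 on U133B, against 9.68 and at most 20. Lower in both were 72 on U133A, against 16.9 and at most 29, and 15 on U133B, within the simulated range (9.20 and at most 17). These simulations hold no day effect. With the spread left after the day is in the model they gave at most 21 higher and 17 lower on U133A, and at most 7 of each on U133B. The 15 lower on U133B lay above that range, so whether they exceed the simulations depends on the day effect. 0 probe sets went opposite ways by that measure, against 0.83 and 0.27 simulated without a day effect, which is too few to tell. With 2 GFP arrays the controls could not be split into parts with 2 arrays each, and part of the excess may come from the shared controls.

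Marker lists of other cell types with enough genes for the test, which were tested on U133A only, did not pass in any comparison. On U133A the prostate basal markers had medians of 0.10 (SOX4 cDNA against GFP, adjusted p = 0.973), -0.08 (SOX4 siRNA against GFP, 0.518) and 0.12 (SOX4 cDNA against SOX4 siRNA, 0.653) over 6 genes. The fibroblast and stromal markers had medians of -0.14 (0.537), -0.06 (0.271) and 0.15 (0.76) over 9 genes. Of the leukocyte markers 4 of 15 were measured, too few for the test, and of these 1 was lower than GFP on both days with the cDNA and 2 with the siRNAs. The markers of luminal cells, which LNCaP cells resemble, had medians of -0.09 (0.617), 0.30 (0.435) and -0.12 (0.219) over 12 genes, and the neuroendocrine and neuronal genes -0.24 (0.537), -0.19 (0.326) and 0.21 (0.76) over 11.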

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

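The tests of explanations in this part were chosen after the results were seen.

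Control probe sets that enter no comparison lay above every GFP array in both arrays of a SOX4 group for 10 of 16 measures compared, where chance alone gives 16.7% for each, and below every GFP array for 4, all of spike-in RNA. The 16 are not independent, since both SOX4 groups were set against the same GFP arrays and both array types read the same RNA. The count of 10 therefore has no chance value of its own. The log2 excess over GFP in ribosomal RNA signal was 4.54 for SOX4 cDNA and 4.37 for SOX4 siRNA on U133A, and 5.05 and 4.96 on U133B. The 3' minus 5' difference of ACTB exceeded GFP by 1.55 (SOX4 cDNA, U133A), 1.43 (SOX4 cDNA, U133B) and 0.33 (SOX4 siRNA, U133B). That of GAPDH exceeded it by 0.46 (SOX4 siRNA, U133A), 0.59 (SOX4 cDNA, U133B) and 0.50 (SOX4 siRNA, U133B).

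Both SOX4 groups shifted alike against GFP although the design was to raise SOX4 in one and lower it in the other. Chance values of the GFP arrays alone were argued against, since differences that share no array still had correlations across probe sets of at least 0.311, and so were opposite SOX4 changes as the source of the shift, since at least 61.9% of probe sets went the same way in such pairs. Spike-in RNA, which does not come from the cells, differed from GFP by -1.33 log2 in the comparison where it differed least, so a difference in labelling or hybridization of the GFP arrays may account for part of the shift. An effect of the GFP cDNA itself on the cells, which is what the groups differ in by design, stays open, and so does a bias with GC content, since no sequences were at hand; neither was tested.

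Hypoxia and glycolysis genes were higher in the SOX4 siRNA group than in either other group. A difference of the GFP arrays was argued against as the whole source. The list's median was -0.73 in SOX4 cDNA against SOX4 siRNA, where no GFP array enters. Relative to SOX4 siRNA, the SOX4 cDNA arrays had weaker 5' signal in ACTB but not clearly in GAPDH. Weaker 5' signal as the whole source was argued against by the median of 0.82 in SOX4 siRNA against GFP. Each of these comparisons holds the arrays of the other source, so both sources acting together were not excluded. Lower SOX4 and the delivery of siRNA as such cannot be told apart, because no array holds a non-targeting siRNA; the median in SOX4 cDNA against GFP, -0.0013, does not decide between them. That lower SOX4 raises these genes may therefore stand only as a hypothesis, and the call rests on the preset correlation of the list test.

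The high-rising SOX4 probe set rose far more with the SOX4 cDNA than the other 4 SOX4 probe sets. A wrong label on a SOX4 cDNA array was argued against, since the lower of these 2 arrays read 14.41 at that probe set. The median difference of the other 4 probe sets was 0.53, which is consistent with their lying outside the transfected sequence while the high-rising one lies inside it. Probe positions were not used here, so this stays a candidate explanation, and no biological explanation was tested.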

How the results depend on the processing

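Most alternatives were planned; the single days of the 2-fold counts, the correlations that share no array and the adjustment over the SOX4 probe sets alone were chosen after the results were seen. SOX4 by its high-rising probe set kept its direction and passed under every alternative in which it was tested, with 1 probe set per gene testing another SOX4 probe set in its place. Named genes kept their direction in all 1971 values under the alternatives, and in 19 of these they newly passed. The filters, the variance settings and the day as a block cannot change a difference, so part of this count was fixed in advance. The genes other than SOX4 were also chosen for a difference of at least 2-fold on both days or for the smallest p. With the day as a replicate block the calls were 1, 0 and 1 on U133A and 0 on U133B in each comparison; the block ended the oxidative phosphorylation call (0.063), added 1 list on U133B for SOX4 siRNA against GFP, and changed no other call.

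The count of 1 probe set became 0 with 1 probe set per gene for SOX4 cDNA against GFP and against SOX4 siRNA on U133A, since that setting leaves the high-rising SOX4 probe set out. For the latter it was 4 with no filter and 1 to 2 without each array in turn (2 without SOX4 cDNA replicate 1). For SOX4 siRNA against GFP the count of 0 on U133A became 1 with a filter at the 60th percentile, 15 with median-centred arrays and 2 with 1 probe set per gene, and on U133B it became 2 with that filter and 2 without a trend. The other counts of probe sets were unchanged without each array in turn.

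The counts at least 2-fold apart, 443, 787 and 448 on U133A and 265, 433 and 124 on U133B, were larger on single days, which ask for 1 difference instead of 2: 1165 without replicate 2 and 2637 without replicate 1, 1653 and 2344, 1510 and 2382, and on U133B 773 and 1246, 918 and 1670, 381 and 871. The correlation against GFP was 0.422 to 0.655 without each array in turn on U133A and 0.472 (without SOX4 cDNA replicate 1) to 0.866 on U133B. Between single-day differences of different days, which share no array, it was 0.311 and 0.350 on U133A and 0.505 and 0.435 on U133B; the cause was not tested.

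Lists that passed numbered 1, 6 and 6 on U133A and 0, 0 and 1 on U133B, and 0 in each with an estimated correlation, where camera's smallest adjusted p was 0.748 (unadjusted p under 0.05: 0, 0 and 1 lists on U133A, 0 on U133B). They numbered 2 with quantile normalization for SOX4 siRNA against GFP on U133A; on U133B they numbered 1 with no filter for SOX4 cDNA against GFP, and 1 with quantile normalization or the mean of a gene's probe sets for SOX4 siRNA against GFP. Without each array in turn they ranged from 1 to 8 for SOX4 cDNA against GFP on U133A (3 without GFP replicate 1, 2 without GFP replicate 2, 3 without SOX4 cDNA replicate 1, 8 without SOX4 cDNA replicate 2) and from 0 to 3 on U133B (1 without GFP replicate 2, 3 without SOX4 cDNA replicate 1). For SOX4 siRNA against GFP they ranged from 2 to 8 on U133A (3 without GFP replicate 2, 2 without SOX4 siRNA replicate 1) and from 0 to 1 on U133B (1 without either of these). For SOX4 cDNA against SOX4 siRNA the range was 3 (without SOX4 siRNA replicate 1) to 7 on U133A. The G2/M median of SOX4 cDNA against SOX4 siRNA ranged from -1.49 (without SOX4 cDNA replicate 1) to 0.10 (without SOX4 cDNA replicate 2). The cause of these changes was not tested. With an estimated correlation fewer lists had an unadjusted camera p under 0.05 than chance alone gives, so that setting could hardly call a list.

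Over the 6 other settings, without the estimated correlation, adjusted p ranged from 2.17e-07 to 5.69e-05 for hypoxia and glycolysis in SOX4 siRNA against GFP and from 2.99e-09 to 6.27e-06 in SOX4 cDNA against SOX4 siRNA, and without each array in turn it was at most 0.000111 and 6.24e-05. For androgen response it ranged from 0.00129 to 0.0155, for TGF-beta and SMAD from 0.00313 to 0.0306 and for hypoxia on U133B from 0.0018 to 0.0205. In SOX4 siRNA against GFP it ranged up to 0.0871 (G1/S), 0.0706 (G2/M), 0.0573 (NF-kappaB), 0.0821 (oxidative phosphorylation) and 0.0573 (splicing), and in SOX4 cDNA against SOX4 siRNA up to 0.0402, 0.0406, 0.0756 and 0.48 for the first 4 of these. Dim probe sets limit what can be seen, since values near background differ little.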

Other observations

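The tests in this part that were chosen after the results were seen are the comparison of probe sets present on both array types and the androgen response genes picked by name.

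Several stress and growth lists lay on the same side on both days without passing. Genes of the unfolded protein response and ATF4, which answer to protein folding stress and amino acid shortage, were higher on both days for 24 of 38 in SOX4 siRNA against GFP on U133A and lower for 10, with 6 at least 2-fold higher and a median of 0.51 (camera adjusted p = 0.216). On U133B 6 of 11 were higher, with a median of 0.43 (0.368). Heat shock proteins had a median of 0.25 (0.313) and cytosolic ribosomal proteins 0.10 (0.619) in that comparison, and PI3K, AKT and mTOR pathway genes 0.43 on U133B (0.151). Apoptosis regulators had a median of 0.29 on U133B in SOX4 cDNA against GFP (0.119), and fatty acid synthesis genes -0.46 on U133A in SOX4 cDNA against SOX4 siRNA (0.206). The Hedgehog pathway, tested on U133B only, had medians of -0.05 (0.831), -0.10 (0.695) and 0.07 (0.817) in the 3 comparisons.

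Further androgen response genes, named after their values were seen, differed in SOX4 cDNA against GFP without passing: FKBP5, a steroid receptor chaperone, by -1.96 ± 0.96 (SE), the kallikrein KLK2 by -1.50 ± 0.54, -2.38 ± 0.70 and 0.16 ± 0.29 by its 3 probe sets, and the protease TMPRSS2 by -1.29 ± 0.45. The corresponding values in SOX4 siRNA against GFP were -0.19, -0.30, -0.57, 0.15 and -0.37.

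The level of the cell-division genes differed between the days on U133A. There the median level of the G2/M genes was 7.58 on day 1 and 6.51 on day 2 in GFP, 7.63 and 6.56 in SOX4 cDNA, and 7.79 and 7.33 in SOX4 siRNA. The G1/S genes were at 8.26 and 7.18, 8.34 and 7.03, and 8.20 and 7.79. On U133B, with 7 genes each, the G2/M genes were at 4.18 and 4.23, 4.13 and 4.17, and 4.10 and 4.15, and the G1/S genes at 6.29 and 5.58, 6.37 and 4.68, and 5.97 and 6.51. Whether the day or the transfection had the larger effect was not tested.

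On both array types 100 probe sets were present, and the same RNA was measured on each. Their differences had correlations between the array types of 0.744 (SOX4 cDNA against GFP), 0.874 (SOX4 siRNA against GFP) and 0.833 (SOX4 cDNA against SOX4 siRNA). On days 1 and 2 alone they were 0.395 and 0.689 for the first and 0.644 and 0.757 for the last; for SOX4 siRNA against GFP the lower of the days had 0.729. Between the days they were 0.282, 0.725 and 0.425 on U133A and 0.441, 0.481 and 0.606 on U133B. Probe sets are not independent replicates.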
